A study of Arabidopsis thaliana with 5 samples.

How the data were processed

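Bisulfite sequencing measures cytosine methylation base by base, because bisulfite converts unmethylated cytosines and leaves methylated ones. Per the labels, genomic DNA came from leaves of 3-week-old Columbia-0 Arabidopsis plants kept in constant light, and the libraries were built for paired-end Illumina sequencing. There were 5 libraries, 1 per genotype: wild type, drm2 (drm2-2), idn2 (idn2-1), the idnl1 idnl2 double mutant (idnl1-1 idnl2-1) and the idn2 idnl1 idnl2 triple mutant (idn2-1 idnl1-1 idnl2-1). With 1 library per genotype no difference has a replicate check, so no p-value between genotypes is given.

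For each cytosine the authors deposited a count of methylated reads, a count of unmethylated reads and a methylation fraction from 0 to 1, with CG, CHG and CHH cytosines (H is A, C or T) listed separately. The column order named in the deposited file headers is the reverse of what the values show: the deposited fraction equals the read count in the column headed unmethylated divided by the sum of both counts. That column was therefore read as methylated reads, which gives CG as the most methylated context. The aligner, the methylation caller, read filters, treatment of duplicate reads and the genome build are not given in the sources used here. All 5 libraries list identical cytosines, each with a depth between 6 and 50 reads, so the authors had filtered by depth before deposit, and a region that lost coverage in 1 library is absent from all. Organelle DNA and the strand of CHH cytosines were not used here.

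The files hold 2563753 CG, 2631018 CHG and 9727770 CHH cytosines on chromosomes 1 to 5. Reads summed over these cytosines came to 296501469 in wild type, 301884478 in drm2, 302869892 in idn2, 297527899 in the double mutant and 200400610 in the triple mutant. Mean depth at CHH cytosines was 19.1, 19.4, 19.8, 19.3 and 12.7 reads in that order, so values of the triple mutant are the least precise. Positions on chromosome 1 run to 30432297, past the end of that chromosome in the annotation at hand, so the builds differ. Coordinates are given as deposited, 1-based, and no gene or transposon was assigned to any of them. The planned gene lists, annotation classes and gene-by-gene values are for that reason not analysed here, and tiles are named by position, which the rule for naming foresaw.

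Genome-wide levels are means of the fraction over cytosines. Levels of regions are methylated reads over all reads in non-overlapping 200-bp tiles with at least 5 CG, 5 CHG or 10 CHH cytosines, averaged over tiles where several are combined. A tile was called lower or higher where it differed from wild type by at least 40 (CG), 20 (CHG) or 10 (CHH) percentage points and passed a two-sided Fisher's exact test on the summed reads, with a Benjamini-Hochberg adjusted p threshold of 0.01 per context. That test compares 2 libraries, not 2 genotypes, and treats reads of neighbouring cytosines as independent although 1 read can cover several. Reads given for a tile are summed over its cytosines, so 1 read that covers several counts several times. From idn2 against the double mutant the variance of tile levels was 2.22 times the binomial one. Intervals are 95% Wilson intervals and cover counting error only; beside a count of 0 the share that 3 counts would make is given instead. Lower tiles in a row, with a gap of at most 1 tile, were joined into regions. The tiles named are the 10 with the largest CHH drop in each mutant, the 5 with the largest rise, and the 5 with the largest drop and rise of the triple mutant against idn2, with a selection printed, made after their values were seen, which holds none of the 5 rises of the double mutant. Only the lists of the 10 largest drops follow the naming rule for tiles as first written; the other lists carry the planned rule for genes over to tiles, a choice made after the data were examined.

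In simulated data with the real depths, 200 tiles changed by a known amount were mixed with unchanged tiles. The changed tiles had wild-type levels of at least 20% CHH, 30% CHG or 50% CG. Reads were drawn without the extra variance given above, so recovery in the real data may be lower. A CHH drop of 20 points was recovered in 93.5% of the 200 tiles at the depth of drm2 and 86.5% at the depth of the triple mutant, and a drop of 10 points, equal to the size limit and so missed in part by that rule alone, in 16.5% and 13.5%. A CG drop of 50 points was recovered in 97.5% and 96.5%, and a CHG drop of 30 points in 91.5% and 78.5%. For overlaps, 20 simulations drew unchanged mutants against the same wild-type library, with the extra variance included.

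The tile width, the size and test rules, the comparisons and the naming of the largest drops were fixed before the data were examined, as were the alternatives of tile width, size, cytosine number, depth and tile weighting. The choices made after the data were examined are the following. Background, meaning cytosines left unconverted or miscalled, was estimated from 70749 tiles with pooled CG and CHG levels under 5%, in place of organelle DNA. No limit was set on CHH in these tiles, so the estimate may include some true methylation. Tiles were classed as unmethylated, CG-only (CG of at least 30%, CHG and CHH under 5%) or all-context (CG of at least 30% and CHG of at least 20%). The pericentromere is the run of 500-kb windows with CHG of at least 20%. CHH-methylated tiles (at least 10% in wild type) were classed by the mean CHG level within 5 kb, and as DRM2-dependent (at least 50% of CHH lost in drm2) or DRM2-independent (under 20% lost). For both, the reads of wild type and drm2 were split at random into a part used to choose the tiles and a part used to measure them, since strand could not serve for this, and levels of these classes have background subtracted. Of the tests of explanations, that of base differences was first written with a clause on gains. It was separated from the rest before the test was run, because the counts of gains had by then been seen. The test of unconverted cytosines on CHG was split by library, and that of CG tiles without CHH was set against its share among all CG tiles, after their values were seen. The test of conversion by mistake was likewise split by library, and the tests of gains and of called tiles after background subtraction were set aside as unable to come out otherwise. Background subtraction on CHG has the same limit. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.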

Results

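DNA methylation was profiled by whole-genome bisulfite sequencing in leaves of wild-type Arabidopsis and 4 mutants of RNA-directed DNA methylation (RdDM), the pathway in which small RNAs guide the methyltransferase DRM2 to its targets. The mutants were drm2 (allele drm2-2), idn2 (idn2-1), which lacks the RNA-binding protein IDN2, the double mutant idnl1 idnl2 (idnl1-1 idnl2-1), which lacks a pair of IDN2-like proteins, and the triple mutant idn2 idnl1 idnl2 of the same alleles. Each genotype had 1 library, so every difference below is between 2 libraries and has no replicate check. Total reads at cytosines were 296501469 in wild type, 301884478 in drm2, 302869892 in idn2, 297527899 in the double mutant and 200400610 in the triple mutant.

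To ask how far each mutation lowers methylation across the genome, mean levels were compared in each sequence context. CHH methylation, part of which depends on RdDM, was 3.19% in wild type and fell in every mutant library, to 2.16% in drm2, 2.05% in idn2, 2.24% in the double mutant and 2.31% in the triple mutant. The drop was present on all 5 chromosomes, with a range of -1.17 to -0.896 points in drm2 and -1.26 to -0.994 points in idn2. In the pericentromere CHH fell from 10.9% to 7.98% in drm2 and 8.22% in idn2, and on the chromosome arms from 1.81% to 1.13% and 0.95%. CHG methylation was 7.81% in wild type and 7.59% in drm2, but 6.15% in idn2, 6.58% in the double mutant and 6.31% in the triple mutant. The small drm2 difference joins a rise of 1.08 points in the pericentromere and a change of -0.42 points on the arms, and it was -0.57 points with tiles weighted alike and -0.12 points with background subtracted. Mean CG methylation lay between 24.9% and 26.4%, with pericentromeric changes of -2.02 points in drm2, -3.02 in idn2, -1.84 in the double mutant and -1.91 in the triple mutant, and a rise of 1.18 points on the arms in drm2. Unmethylated tiles read 0.952% CHH in wild type, 0.864% in drm2, 0.487% in idn2, 0.613% in the double mutant and 0.687% in the triple mutant, so part of these differences may be background. These tiles were chosen without a limit on CHH, so their level may also hold some true methylation. With that level subtracted, CHH was 2.26% in wild type, 1.31% in drm2, 1.57% in idn2 and 1.64% in the double and triple mutants, which makes drm2 and not idn2 the lowest.

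**Figure D1:**
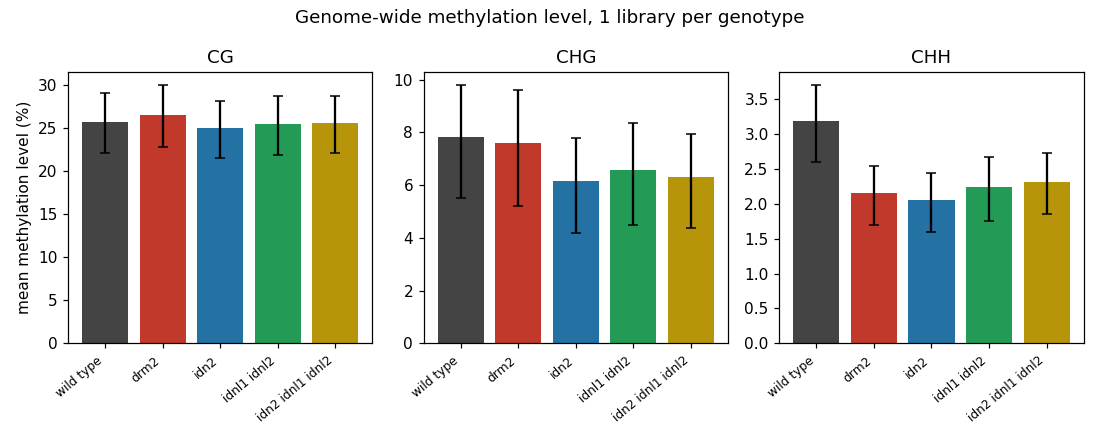
Mean methylation level (%) of each library in CG, CHG and CHH contexts; bars are genome-wide means and error bars span the lowest and highest of the 5 chromosomes. CHH falls from 3.19% in wild type to between 2.05% and 2.31% in the mutants.

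**Figure D2:**
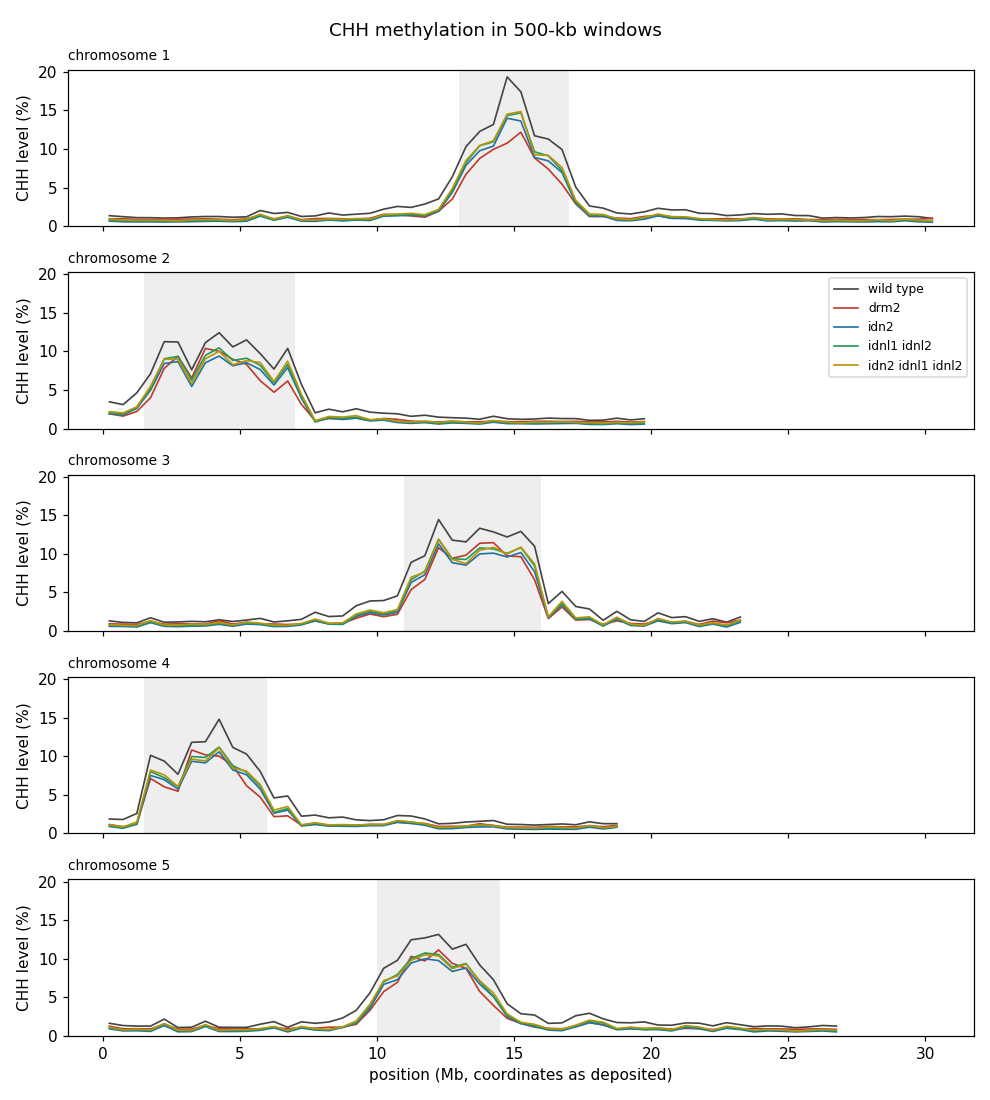
CHH level (%) in 500-kb windows along each chromosome, with position in Mb as deposited, a line per library and the pericentromere shaded. The wild-type mean is the highest of the 5 libraries in the pericentromere, at 10.9%, and on the arms, at 1.81%, although drm2 lies slightly above it in the last window of chromosome 1.

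The regions that lost methylation were then located in 200-bp tiles. Of 434601 tiles tested for CHH, 11136 were lower in drm2, 7736 in idn2, 7549 in the double mutant and 7087 in the triple mutant, against 690, 31, 57 and 181 higher ones. Unchanged libraries simulated at the same depths gave means of 31.8, 28.0, 31.1 and 39.0 lower and 138.5, 135.2, 138.7 and 204.5 higher tiles. In higher tiles only drm2 exceeded this simulation. The simulation gave more higher tiles than idn2 and the double mutant held, so it seems to overstate noise in that direction. It therefore cannot show whether the 181 higher tiles of the triple mutant are noise. The lost tiles lay in short stretches: 64.1% of the 6750 regions in drm2 and 69.1% of the 5411 in idn2 were a single tile, while the longest spanned 7200 bp in drm2 and 3200 bp in idn2. Pericentromeric tiles made up 38.2% of the drm2 calls and 35.2% of the idn2 calls, compared with 13.4% of all tiles tested but 72.1% of the 37696 tiles with at least 10% CHH in wild type, the ones that could lose 10 points. Of those 37696, drm2 was lower at 15.7% in the pericentromere and 65.4% on the arms, and idn2 at 10% and 47.6%. CHG fell with CHH. At tiles lower in CHH with at least 5 CHG cytosines, CHG went from 58.3% to 32.9% in drm2 (4451 tiles). In idn2 it went from 57.2% to 32.6% (2799 tiles). CG changed less at the tiles lower in CHH with at least 5 CG cytosines. In drm2 the mean went from 85.8% to 72.7% (5551 tiles) and in idn2 from 83.8% to 77.2% (3801 tiles). In the triple mutant it went from 83.4% to 80.7% (3598 tiles). The drm2 mean does not describe the typical tile: its median was 87.6%, and 66.0% of the tiles were lower than in wild type. Tiles under 5% CG numbered 595 (10.7%) in drm2, against 40 in wild type.

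**Figure D3:**
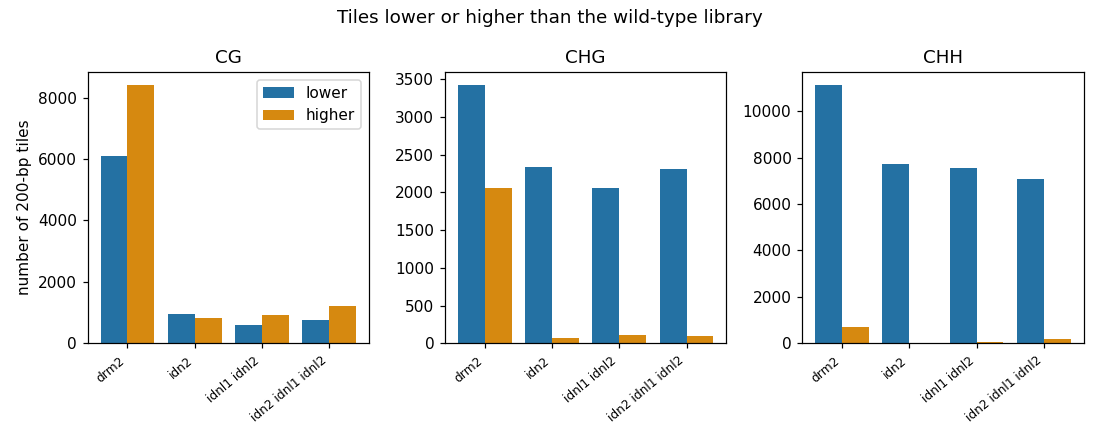
Number of 200-bp tiles lower (blue) or higher (orange) than the wild-type library in CG, CHG and CHH for each mutant. In CHH the lower tiles number 7087 to 11136, while in CG the drm2 library has 6102 lower and 8415 higher tiles.

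The 10 tiles with the largest CHH drop in each mutant went from at least 70.7% in wild type to at most 16.9% in that mutant. These tiles, 23 distinct ones together, were called lower in all 4 mutants, and few lay in the pericentromere (0 of drm2, 2 of idn2, 1 of the double mutant and 1 of the triple mutant). Read counts of tiles here are sums over their CHH cytosines, so they exceed the number of separate reads. On chromosome 1 the tile at 25269601 to 25269800 read 76.2% in wild type (95% interval 72.2 to 79.7, 487 reads), 1.9% in drm2, 2.9% in idn2, 2.1% in the double mutant and 5.5% in the triple mutant. On chromosome 5 the tile at 8241401 to 8241600 read 75.6% in wild type (72.2 to 78.7, 656 reads), 3.3% in drm2, 2.4% in idn2, 1.2% in the double mutant and 5.5% in the triple mutant. Among the tiles with the largest drop in drm2, some kept more methylation without the IDN proteins. At 19535001 to 19535200 on chromosome 2, CHH was 90.5% in wild type (87.7 to 92.8, 518 reads) and 0.5% in drm2 (0.1 to 2.9), but 54.2% in idn2 (48.7 to 59.5), 54.7% in the double mutant and 56.7% in the triple mutant. The tile at 29268201 to 29268400 on chromosome 1 fell from 91.9% to 1.2% in drm2, 23.8% in idn2, 16.9% in the double mutant and 25% in the triple mutant. Among the tiles with the largest drops in the IDN mutants, some went the other way: at 2608001 to 2608200 on chromosome 4, CHH fell from 75.3% to 6.4% in drm2 (3.8 to 10.6), 1.7% in idn2 (0.6 to 5.0) and 0.9% in the double mutant (0.2 to 3.2). Of the rises, the 5 largest in drm2 were called higher in none of the other mutants. At 22572801 to 22573000 on chromosome 3, CHH was 1.9% in wild type and 37.3% in drm2 (482 reads, against 206 in wild type), with 0 methylated of 236 reads in idn2 (3 counts would be 1.27%), 0 of 247 in the double mutant (1.21%) and 0 of 155 in the triple mutant (1.94%). Among the largest rises in idn2 and the triple mutant, the tile at 5988201 to 5988400 on chromosome 4 read 5.9% in wild type (3.7 to 9.4, 269 reads), 21.7% in drm2, 27.0% in idn2, 24.0% in the double mutant and 32.7% in the triple mutant, so the wild-type library is the one that stands apart there.

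Whether the IDN proteins act where DRM2 acts was examined at the 11136 tiles lower in drm2. Their mean CHH level was 28.4% in wild type, 4.5% in drm2, 10.8% in idn2, 10.6% in the double mutant and 11.7% in the triple mutant. The share of the wild-type level lost was thus 84.1% in drm2, 62.1% in idn2 (59.9% to 63.8% over the 5 chromosomes), 62.6% in the double mutant (59.9% to 64.4%) and 58.9% in the triple mutant (55.7% to 61.0%). Tiles left under 5% CHH made up 68.8% in drm2, 35.5% in idn2, 37.6% in the double mutant and 34.7% in the triple mutant. At the 4451 of them with at least 5 CHG cytosines, CHG went from 58.3% to 40.3% in idn2, 40.8% in the double mutant and 40.2% in the triple mutant. The 11136 tiles were chosen for a difference between drm2 and the wild-type library that also serves the other comparisons. When drm2 was instead compared with the double mutant to choose 2913 tiles, the loss was 37.1% in idn2 and 28.5% in the triple mutant, a choice that favours tiles kept in the double mutant.

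**Figure D4:**
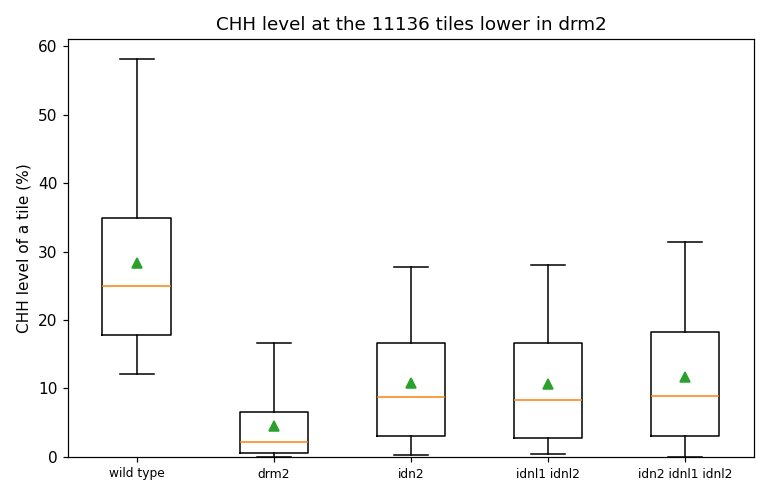
CHH level (%) per tile at the 11136 tiles lower in drm2, by library; boxes span the quartiles with the median as a line and the mean as a triangle, and whiskers reach the 5th and 95th percentiles. Means are 28.4% in wild type, 4.5% in drm2 and 10.6% to 11.7% in the other mutants.

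The tiles lost in the different mutants were largely shared. Of the tiles lower in CHH in idn2, 7215 (93.3%) were also lower in drm2, and the same held for 7177 (95.1%) of those of the double mutant and 6675 (94.2%) of those of the triple mutant. Independent lists of these sizes among the 37696 tiles with at least 10% CHH in wild type would share 2285.3, 2230.1 and 2093.6 tiles, and unchanged libraries simulated against the same wild type shared 1.2, 1.1 and 1.2, with lists of only 28.0 to 39.0 tiles that by their size could share few. Among the IDN mutants, idn2 and the double mutant shared 6806 tiles, against 1549.2 for independent lists. All 4 mutants shared 6048 tiles, and 3191 were lower in drm2 alone. Of the CHH tiles lower in drm2 with enough CG cytosines, 13.0% were also called lower in CG. In idn2, the double mutant and the triple mutant this share of their own lists was 3.7%, 1.2% and 1.8%. The drm2 list thus holds more tiles that also lost CG methylation, but CG losses were more frequent in drm2 everywhere. Of all CG tiles tested, 2.69% were lower in drm2, 0.417% in idn2, 0.269% in the double mutant and 0.338% in the triple mutant. At the 3921 tiles called in drm2 but not in idn2, CHH read 5.4 points below wild type in idn2 (a change of -5.4, against -14.4 in drm2). These tiles were chosen with the same wild-type reads, so part of that change may come from the choice. Because 1 wild-type library served every list, part of the excess of shared tiles over independent lists may come from it. With separate parts of its reads used for the lists, the overlaps were 6582, 6554 and 5956 tiles. This split removes shared counting error only. Any trait of the wild-type plants or library itself stays in both parts, so its share in the overlap cannot be told.

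The factorial part of the design asks whether removing IDNL1 and IDNL2 matters when IDN2 is already gone. At the 11136 drm2 tiles, loss of IDNL1 and IDNL2 changed CHH by -17.75 points in a wild-type background (-18.33 to -17.15 over the chromosomes) and by 0.91 points in the idn2 background (0.75 to 1.23). At the 2913 tiles where drm2 was lower than the double mutant, which favours tiles kept in the double mutant, these effects were -9.8 and 2.69 points. Loss of IDN2 changed it by -17.61 points in wild type and by 1.06 points in the idnl1 idnl2 background. The triple mutant therefore had no lower mean level at these tiles than either parent genotype. Room for a further loss was small at many of them, since 35.5% already read under 5% CHH in idn2 and 37.6% in the double mutant. Across the genome the triple mutant had 181 lower and 295 higher CHH tiles than idn2, 120 lower and 83 higher CHG tiles, and 292 lower and 704 higher CG tiles. With CHH differences of at least 20 points the balance turned, to 47 lower and 30 higher tiles. Over all CHH tiles, idn2 was higher than drm2 at 2809 and lower at 1031.

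Single tiles departed from this average in both directions. Where the triple mutant was furthest below idn2, idn2 kept much of its methylation and the double mutant did not. At 7328001 to 7328200 on chromosome 5, CHH was 63.0% in wild type, 46.7% in idn2 (42.5 to 51.0), 9.5% in the double mutant and 8.5% in the triple mutant (5.5 to 12.9). At 16563001 to 16563200 on chromosome 2 it was 61.8%, 46.1%, 2.4% and 2.5% in the same order. At 1441401 to 1441600 on chromosome 1 it was 39.7%, 48.6%, 6.4% and 8.5%. Where the triple mutant was furthest above idn2, idn2 had the lowest level of the IDN mutants. Both sets were chosen for their difference between the triple mutant and idn2. The tile at 15926801 to 15927000 on chromosome 3 read 76.8% in wild type, 0.3% in idn2 (0.1 to 1.7), 60.4% in the double mutant and 57.8% in the triple mutant (53.3 to 62.3). The tile at 9525401 to 9525600 on chromosome 2 read 57.3%, 1.5%, 31.3% and 47.7%.

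Dependence on the pathway varied with the methylation of the surrounding sequence, here with background subtracted from the CHH levels. The 5968 CHH-methylated tiles with under 10% CHG within 5 kb lost 94.1% of their CHH in drm2, 76.2% in idn2, 78.9% in the double mutant and 75.1% in the triple mutant. The 27073 tiles with 30% or more CHG around them lost 28.8%, 20.1%, 15.6% and 14.6%. Tiles with 10 to 30% CHG nearby lay between, at 71.1%, 47.4%, 47.0% and 44.3%. In CG-only tiles, a class typical of gene bodies, CG was 67.0% in wild type, 68.3% in drm2, 66.9% in idn2, 67.8% in the double mutant and 69.0% in the triple mutant.

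The drm2 library differed from wild type in CG methylation in both directions. It had 6102 lower and 8415 higher CG tiles out of 226587, while idn2 had 944 and 826, the double mutant 609 and 932, and the triple mutant 766 and 1219. At the lower tiles CG went from 71.7% in wild type to 9.5% in drm2, with 65.6% in idn2, 67.5% in the double mutant and 68.3% in the triple mutant. At the higher tiles it went from 11.1% to 73.5%, with 15.1%, 15.6% and 16.2% in the other mutants. CHG also changed in both directions in drm2, with 3425 lower and 2064 higher tiles, against 2339 and 76 in idn2.

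**Figure D5:**
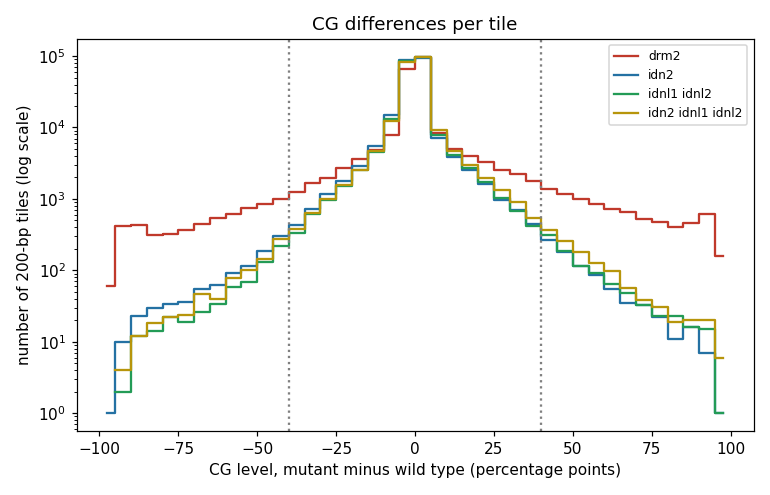
Number of 200-bp tiles (log scale) by the difference in CG level from wild type in percentage points, a line per mutant; dotted lines mark 40 points on either side. The drm2 library has 6102 tiles below and 8415 above these limits that also pass the test, against 944 and 826 in idn2.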

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

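The contrast below between backgrounds was part of the design; no test of the difference between backgrounds was made, since each genotype had 1 library. The effect of removing IDNL1 and IDNL2 on CHH at the drm2 tiles went in opposite directions: -17.75 points in a wild-type background and 0.91 points in the idn2 background. Likewise the effect of removing IDN2 was -17.61 points in wild type and 1.06 points in the idnl1 idnl2 background. The triple mutant read above idn2 elsewhere too. Over the whole genome CHH was 2.31% against 2.05%, and in unmethylated tiles 0.687% against 0.487%. With background subtracted, CHH-methylated tiles with 30% or more CHG nearby read 14.9% against 13.9%. The 0.91 points in the idn2 background thus show no further loss, and do not show a rise tied to the drm2 tiles. The triple mutant had the lowest depth of the 5 libraries.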

How the results depend on the processing

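The alternatives of background subtraction, size rule alone, mean over cytosines, split reads and another reference for the drm2 tiles were chosen after seeing the data; the others were planned. Libraries are listed in the order drm2, idn2, double mutant, triple mutant. With each tile weighted alike, the genome-wide level differed from wild type in CG by 0.84, -0.86, -0.37 and -0.25 points, in CHG by -0.57, -1.76, -1.35 and -1.64 points, in CHH by -1.18, -1.21, -1.05 and -1.0 points. With background subtracted, the genome-wide level differed from wild type in CG by -0.40, -0.02 and 0.09 points (idn2, double mutant, triple mutant), in CHG by -0.12, -1.24, -0.91 and -1.24 points, in CHH by -0.95, -0.69, -0.62 and -0.62 points. The CG difference of the triple mutant thus reversed, and the cause was not tested beyond the subtraction itself. In 500-bp tiles, tile counts that moved over 1.5 times included CG lower 3621, 387, 207 and 277, CG lower 74 (triple against idn2), CG higher 5452 (drm2), CG higher 275 (triple against idn2), CHH lower 7416 (drm2), CHH lower 76 (triple against idn2), CHH higher 282 (drm2), CHH higher 117 (triple against idn2). With larger size limits, tile counts that moved over 1.5 times included CG lower 460, 257 and 350 (idn2, double mutant, triple mutant), CG lower 113 (triple against idn2), CG higher 346 (triple against idn2), CHG lower 1107, 1120 and 1193 (idn2, double mutant, triple mutant), CHG lower 65 (triple against idn2), CHG higher 1268 (drm2), CHG higher 37 (triple against idn2), CHH lower 5051, 3776, 3888 and 3696, CHH lower 47 (triple against idn2), CHH higher 64 (drm2), CHH higher 30 (triple against idn2). With more cytosines per tile, tile counts that moved over 1.5 times included CG lower 1234, 129, 66 and 95, CG lower 34 (triple against idn2), CG higher 1370 (drm2), CG higher 113 (triple against idn2), CHG lower 709, 448, 414 and 570, CHG lower 57 (triple against idn2), CHG higher 390 (drm2), CHG higher 21 (triple against idn2), CHH lower 5520, 3573, 3461 and 3379, CHH lower 87 (triple against idn2), CHH higher 284 (drm2), CHH higher 182 (triple against idn2). With a depth of at least 10, tile counts that moved over 1.5 times included CG lower 3510, 462, 278 and 344, CG lower 136 (triple against idn2), CG higher 4235 (drm2), CG higher 385 (triple against idn2), CHG lower 1852, 1204, 1006 and 1263, CHG higher 1167 (drm2), CHG higher 51 (triple against idn2), CHH lower 6369, 3911, 3821 and 3529, CHH lower 100 (triple against idn2), CHH higher 148 (triple against idn2). In 100-bp tiles, tile counts that moved over 1.5 times included CHH higher 675 (triple against idn2). With the size rule alone, tile counts that moved over 1.5 times included CHG lower 228 (triple against idn2), CHG higher 204 (triple against idn2), CHH higher 634 (triple against idn2). Of the counts of higher tiles in idn2, the double and the triple mutant against wild type, 29 more fell by over 1.5 times in these settings, while in 100-bp tiles CHH higher rose to 60, 98 and 426. In CHH the balance of lower and higher tiles of the triple mutant against idn2 reversed with larger size limits, from 38.0% lower to 61.0%, and the cause was not tested. The loss at drm2 tiles in 100-bp tiles was 81.9%, 58.5%, 58.6% and 54.7%, and the effect of idnl1 idnl2 was -17.29 points in wild type and 1.1 points in idn2. In 500-bp tiles that loss was 85.1%, 63.6%, 64.2% and 60.2%, and the effect of idnl1 idnl2 was -16.60 points in wild type. It was, with a difference of 20 points, 92.5%, 72.0%, 73.9% and 69.7%, and the effect of idnl1 idnl2 was -28.70 points in wild type. With at least 20 cytosines it was 80.5%, 57.6%, 57.7% and 53.8%, and the effect of idnl1 idnl2 was -16.33 points in wild type and 1.08 points in idn2. Background subtraction gave a loss of 86.7%, 62.7%, 63.6% and 60%, and the effect of idnl1 idnl2 was -17.62 points in wild type and 0.74 points in idn2. For tiles chosen and measured on separate reads it was 86.1%, 64.2%, 65.1% and 61.3%, and the effect of idnl1 idnl2 was -18.77 points in wild type. For drm2 tiles called against the double mutant it was 81.7%, 37.1%, 31.3% and 28.5%, with effects of idnl1 idnl2 of -9.8 points in wild type and 2.69 points in idn2. With a difference of 20 points, the idn2, double and triple mutant shared 3695, 3804 and 3607 tiles with drm2. With at least 20 cytosines, the idn2, double and triple mutant shared 3324, 3286 and 3152 tiles with drm2. Fewer counts with larger tiles, limits or minimums follow from fewer tiles tested or a stricter rule; other causes were not tested. Another 108 values of main results stayed within 1.5 times or their counting interval, and the changes at named tiles kept direction and side of the threshold in all 161 values that could be computed under a depth of at least 10, background subtraction and the mean over cytosines. Not run were every cytosine of each library and the cytosines of each pair (the same in all files), organelle correction, the strand split, gene flanks and gene lists. Depth limits the triple mutant more than drm2: simulated CHG drops of 30 points were recovered in 78.5% of tiles at its depth and 91.5% at that of drm2. Another 19 values, on surrounding CHG and on DRM2-independent tiles, moved past their counting interval in other tile widths and kept their direction.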

Other observations

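CHG methylation outside the DRM2-dependent tiles moved apart between the mutants. With background subtracted, at the 8088 DRM2-independent tiles with enough CHG cytosines, 54.0% CHG in wild type became 58.7% in drm2, a rise of 4.7 points, but 47.2% in idn2, 50.4% in the double mutant and 47.9% in the triple mutant. These tiles were chosen because drm2 kept its CHH there: the drm2 change, also after subtraction, was 1.5 points at intermediate tiles and -0.09 points over all all-context tiles. Of the DRM2-independent tiles, 92.2% lie in the pericentromere. Some long regions lost nearly all methylation in every context in the drm2 library and far less in the others. The region at 5800001 to 5805600 on chromosome 2 went from 90.4% CG, 62.4% CHG and 17.5% CHH in wild type to 7.3%, 1.6% and 1.5% in drm2, with 86.3%, 55.8% and 15.6% in idn2 and 88.0%, 61.4% and 17.0% in the double mutant. The region at 8276801 to 8281600 on chromosome 2 went from 91.2% CG, 59.6% CHG and 20.6% CHH to 4.7%, 1.0% and 1.0% in drm2, and to 87.5%, 51.7% and 15.3% in idn2.

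The tests on CHG outside the DRM2-dependent tiles, the test on gains among the CG differences, the tests of unconverted cytosines from the mean CHH level, and the base share of CG tiles without CHH were chosen only after the results were seen; the other tests below were written before.

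For the CG differences of the drm2 library in both directions, one rate of unconverted cytosines per library is argued against: it cannot exceed the mean CHH level, at most 3.19%, while the calls need 40 points. That 101.6% as many tiles were called after background subtraction decides nothing, since so small a shift could not move them, and neither do gains 10.2 times those of idn2, which restate the pattern. For the losses, lone lost CG dinucleotides were 3.85 times as frequent in drm2 as in idn2 (0.651% against 0.169%), between the bounds set beforehand for and against C-to-T differences, so this stays open as a source of some. Inherited CG differences unrelated to DRM2 targets may be another: 65.4% of the called tiles had under 2% CHH in every library, above the level set beforehand, but 69.7% of all CG tiles did too, so this share decides nothing. An effect of the drm2 mutation itself, with 1 library, also stays open and untested.

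The idn2, double and triple mutant libraries share a lower CHG level in 15275 all-context tiles not called lower in drm2. These tiles are not shown to be independent of DRM2. With background subtracted, they lost 16.9% of their CHH in drm2, 15.3% in idn2, 10.6% in the double mutant and 10.2% in the triple mutant. After the same subtraction CHG fell by 6.56 points or more in idn2 and the triple mutant. The subtraction alone decides nothing, since unmethylated tiles read only 0.919% CHG in wild type and 0.455% in idn2. One rate of unconverted cytosines is argued against there, since it cannot exceed the mean CHH level of wild type, 3.19%. In the double mutant CHG fell by 3.88 points (-4.35 to -3.43 over the chromosomes). That is above 3.19 points but short of the bound of 4 points chosen against unconverted cytosines, so there the test is unresolved. Conversion of methylated cytosines by mistake at one rate, which needs CHG and CG to lose equal shares, is argued against in idn2 and the triple mutant, with ratios of 3.59 or more. In the double mutant the ratio was 3.05 (2.66 to 3.63 over the chromosomes), which did not clear the bound of 3 on every chromosome. By that rule the test is unresolved there. It leans the same way, since CHG lost a larger share than CG on every chromosome. A single library deposited 3 times is argued against, since each pair differed at 534 or more CG tiles. A batch and the genotypes cannot be told apart: these libraries also read lower in unmethylated tiles, by a gap of 0.176 points in CHH, but they are also all the IDN mutants, so a role of the IDN proteins in CHG there is an open hypothesis.

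The drm2 library had 690 tiles with higher CHH than wild type. One rate of unconverted cytosines is argued against, since it cannot exceed the mean CHH level of drm2, 2.16%, and a gain needs 10 points; the count after background subtraction, 104.3% of that before, decides nothing, since the shift was too small to move it. Of the 340 with enough CG cytosines, 74.1% also gained at least 40 points in CG, compared with 3.7% of all CG tiles. This is what whole tiles gaining methylation in all contexts in this line would give, possibly by inheritance, but inheritance itself was not tested. At the 5 largest gains drm2 also had more reads than wild type, although the total reads of these libraries were close. It had 273, 482, 755, 342 and 430 reads there, against 249, 206, 333, 249 and 250 in wild type. The cause of these extra reads was not tested.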
